A study of Homo sapiens with 8 samples.

How the data were processed

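The samples were 8 iCLIP libraries from Flp-In T-REx 293 cells that express 3xFLAG-DUS1L or 3xFLAG-DUS2L on tetracycline. Per the labels' protocols, tetracycline (1 µg/mL) was present for 12 h before the medium was replaced, and for another 12 h with or without 100 µM 5-chlorouridine (5-ClUrd). Each of the 4 groups had 2 libraries, which the series describes as biological replicates.

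The deposited site files give a raw whole-number count for each single-nucleotide crosslink site and strand, one file per library, and no normalization was found in the values. The deposited peak files give intervals of 2 to 6 nt whose score of at least 10 equals the summed count of the same library's sites inside, in 1680 of 1680 peaks. STAR 2.7.0f and the hg38 build were used, per the submitters' processing notes. Peak calling, handling of molecular identifiers and filters are not given in the sources used here. The names of the deposited DUS2L site files mention premapping to non-coding RNAs and those of DUS1L do not, so the making of the files may differ between the enzymes. Site counts did not exceed 1436 in any library, and intervals on counts cover counting error only.

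Sites lay on 252 tRNA references, which name 413 genes, on the 45S pre-rRNA and on 5S rRNA. Of the gene names, 390 matched a symbol in the RefSeq annotation of GRCh38.p14, the source of the coordinates. Counts on the sense strand were summed to 50 tRNA families, one per amino acid and anticodon, and 5 rRNA families (18S, 28S, 5.8S, 5S and the 45S spacers). Near-identical copies share reads, so that single genes are not reported. Antisense counts, between 0.298% and 1.27% of a library, were left out. Lists planned for mitochondrial tRNA, small nuclear and nucleolar RNA, other RNA polymerase III transcripts and mRNA had no members in the files, and lists by the base at positions 16, 17, 20 and 47 need sequences that were not at hand; these were not analysed here. Positions were counted from 1 at the 5′ end of the reference.

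Families and sites with at least 10 counts over the fitted libraries were tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Libraries were scaled to their total sense counts, because TMM assumes that most families do not change. 5-ClUrd was compared with untreated within each enzyme's 4 libraries. The difference between these effects and the comparison of treated libraries came from one fit of all 8. Lists were tested with camera at a preset correlation of 0.01 (limma 3.58.1) and again with an estimated correlation. Shares are means with SD per group, compared by an exact two-sided permutation test. Peaks were intersected on the same strand with bedtools 2.31.1. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

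The tests, lists and named families were fixed before the data were examined. The rule named the 12 families with the largest rise and the 8 with the largest fall among those past the threshold and separated in every library, filled up to 20 with the families of highest treated share. It also named the 10 sites of highest treated share per enzyme, and 5 families in each direction between enzymes. For sites, scaling to the sum of tRNA site counts was first run by mistake and corrected to the fixed design after those results had been seen.

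Alternatives were TMM factors, DESeq2 1.42.0 size factors and its Wald test, minimum counts of 1 and 50, the replicate number in the model, all 8 libraries in one fit, tRNA families alone, and each library left out. Added after the data were seen were leaving out sites above 500 counts in any library, both strands, and the tRNA site scaling. With a library left out, the lone library of its group is assumed to vary like the other groups.

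The fits were tested on simulated data made from the real means and library sizes. A minority of features was changed, equally often up and down, with no limit on the count per site. The rates therefore do not speak to the choice of scaling or to such a limit. Of simulated 4-fold and 8-fold changes, 37.8% and 75.2% were recovered for DUS1L families, 94.2% and 94.2% for DUS2L families, 38.3% and 75.8% for the difference of effects, and 85% and 96.7% between treated libraries. For sites it was 4.57% and 16.3% in DUS1L, and 20.8% and 58.7% in DUS2L. The share of false calls was 5% for DUS1L families, 8.50% for DUS2L families, 4.86% for the difference, 5.63% between treated libraries, 7.22% for DUS1L sites and 2.83% for DUS2L sites. Replicates differed beyond sampling noise: the chi-square per degree of freedom was between 54.9 and 285 over families, and log2 family shares correlated at 0.875 and 0.989 in DUS1L (untreated, treated) and 0.994 and 0.967 in DUS2L.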

Results

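Crosslink sites of 2 human dihydrouridine synthases, DUS1L and DUS2L, were mapped by iCLIP (individual-nucleotide crosslinking and immunoprecipitation). Dihydrouridine synthases reduce uridine to dihydrouridine, a modification found mainly in the D loop of tRNA. The cells were Flp-In T-REx 293 cells, a line derived from human embryonic kidney, with a tetracycline-inducible 3xFLAG-tagged copy of either enzyme. Each enzyme was sampled with and without 5-chlorouridine (5-ClUrd), a uridine analogue that cells build into RNA and that can trap such enzymes on their target bases. This gave 4 groups of 2 libraries, and the series describes the replicates as biological. The question was which RNAs, and which positions in them, each enzyme contacts when the analogue is present.

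Total crosslink counts differed widely between libraries. Untreated DUS1L libraries held 145380 and 7395 counts, and 5-ClUrd DUS1L libraries held 830326 and 545710. Untreated DUS2L libraries held 130576 and 172804 counts, and 5-ClUrd DUS2L libraries held 371986 and 367701. A share of 3 counts corresponds to 0.0407% of sense counts in the second untreated DUS1L library, and to at most 0.00231% in any other library. Statements on DUS1L therefore rest on a thinner untreated baseline than those on DUS2L.

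The deposited sites lay on cytosolic tRNA and rRNA only, so that shares are of these RNAs together and not of all RNA. Within them, cytosolic tRNA took nearly all DUS1L counts with or without the analogue. Its share of DUS2L counts was higher with the analogue. In DUS1L cells the tRNA share was 99.1% ± 0.585 untreated, and rRNA took 0.903% ± 0.585 untreated and 0.957% ± 0.176 with 5-ClUrd (SD, n = 2 each). In DUS2L cells the tRNA share was 83.5% ± 4.05 untreated and 96.5% ± 1.26 with 5-ClUrd (SD, n = 2 each), a difference of 13.0 percentage points. Most of the remaining untreated DUS2L counts lay on 28S rRNA (12.3% ± 3.07), the large-subunit ribosomal RNA, and 18S rRNA (2.96% ± 0.720). These fell to 2.40% ± 0.862 and 0.597% ± 0.176 (SD, n = 2 each). The ribosomal reference was the 45S transcription unit RNA45SN1 on chromosome 21 (8433222 to 8446572) with RNA5S1 on chromosome 1 (228610266 to 228610386, hg38). An exact two-sided permutation test gave p = 0.33333 for DUS2L, the smallest value that 2 against 2 libraries allow, and p = 1 for DUS1L. Counting each site once gave differences of -8.69 points in DUS1L and 19.6 points in DUS2L.

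**Figure D1:**
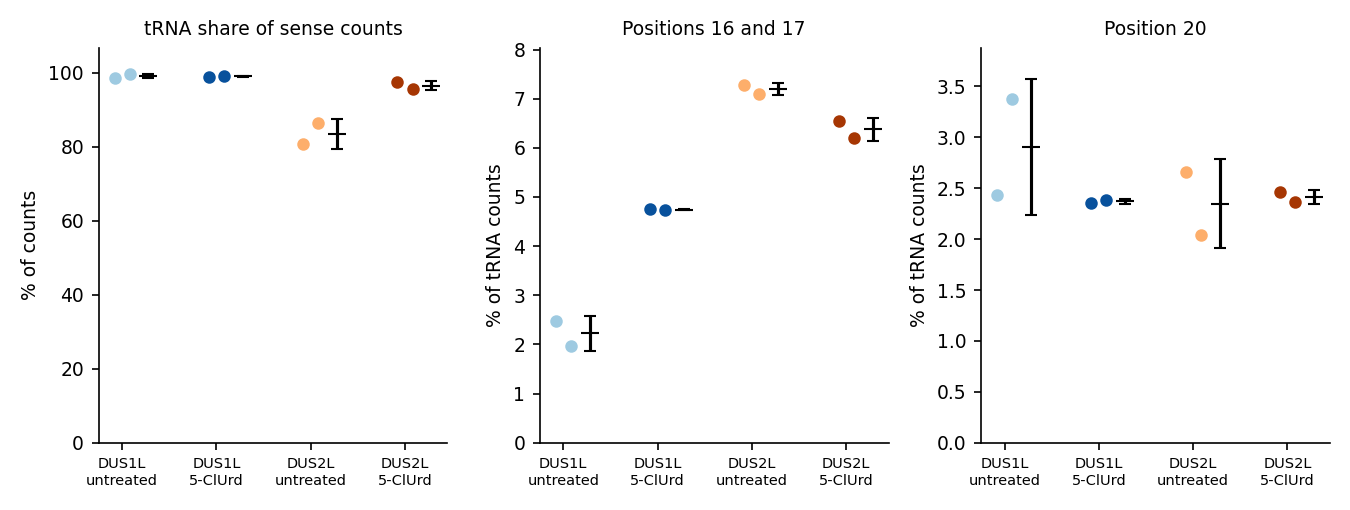
Shares per library in the 4 groups, with points for libraries and a bar with whiskers for the mean and SD (n = 2). The panels show the tRNA share of sense counts (%), and the share of tRNA counts (%) at positions 16 and 17 and at position 20; both treated DUS2L libraries lie above both untreated ones in the tRNA share (96.5% against 83.5% on average).

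In DUS1L cells, 2 of 3 alanine, 2 of 3 threonine, both glutamine and 2 of 5 leucine tRNA families rose with 5-ClUrd, and tRNA-Arg-TCG fell. tRNA-Arg-TCG was the leading untreated family, and it went from 20.9% ± 0.414 to 6.17% ± 0.0748 of counts (SD, n = 2 each), a log2 fold change of -1.76 ± 0.10 (SE; adjusted p = 5.45e-05). 5 of its 6 genes had a position in the annotation, among them TRR-TCG1-1 on chromosome 15 (89335073 to 89335145) and TRR-TCG3-1 on chromosome 17 (75035113 to 75035185). tRNA-Ala-AGC rose from 2.25% ± 0.662 to 7.66% ± 0.493 (log2 1.78 ± 0.31, adjusted p = 0.0243). tRNA-Thr-AGT rose from 0.450% ± 0.0416 to 2.65% ± 0.0911 (log2 2.55 ± 0.58, adjusted p = 0.0347).

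By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 12 of 53 families rose and 1 fell, and all 13 were separated in every treated against every untreated library, as chance alone would do for a share of 0.333. tRNA-Gln-CTG rose by 3.25, tRNA-Asp-GTC by 2.91, tRNA-Ala-CGC by 2.73, tRNA-Thr-CGT by 2.56 and tRNA-Asn-GTT by 1.35 on the log2 scale. tRNA-Leu-TAG rose by 3.37 from a mean of 0.0113% of untreated counts. tRNA-Gly-TCC (log2 4.68) and tRNA-Glu-CTC (log2 3.75) rested on 7 and 6 untreated counts. tRNA-Gln-TTG had 1 untreated and 638 treated counts, a ratio of 70.8 with a 95% counting interval of 12.7 to 2800. tRNA-Leu-AAG had 1 untreated and 199 treated counts, a ratio of 22.1 with an interval of 3.92 to 876.

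The other families with the highest treated shares did not pass the threshold. tRNA-Arg-CCT held 9.14% ± 0.539 and tRNA-Arg-TCT 8.76% ± 0.142 of treated counts, with log2 changes of -0.17 and -0.34. tRNA-Lys-CTT (0.57) and tRNA-Lys-TTT (0.90) were positive with the total-count scaling and negative with trimmed-mean (TMM) and DESeq2 scalings. tRNA-Phe-GAA (-1.32), tRNA-Arg-ACG (-0.95) and tRNA-Val-CAC (-1.06) had adjusted p of 0.152, 0.0615 and 0.0615. Without the first untreated library tRNA-Arg-TCT passed as a rise (0.37, adjusted p = 0.0258); the sign of tRNA-Lys-CTT turned as well (-0.13), and that of tRNA-Phe-GAA without the second (0.23). tRNA-Lys-TTT (1.54) and tRNA-Phe-GAA (-2.06) passed without the first, and tRNA-Lys-CTT (1.93) without the second. With TMM factors tRNA-Arg-CCT (-1.21), tRNA-Arg-TCT (-1.40), tRNA-Phe-GAA (-2.31), tRNA-Arg-ACG (-1.97) and tRNA-Val-CAC (-2.11) passed as falls.

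The DUS1L split depended on the scaling, since the median family moved by -1.03 with TMM factors and by -1.25 with DESeq2 size factors. TMM gave 2 rises and 8 falls, DESeq2 size factors 1 and 9, and DESeq2's Wald test 2 and 10. The fall of tRNA-Arg-TCG passed in all 3; tRNA-Gln-TTG rose with both scalings in edgeR, tRNA-Gly-TCC with TMM, and tRNA-Gln-CTG and tRNA-Ala-CGC in DESeq2's Wald test. Without the first treated library 2 families passed and without the second 1, in both cases falls including tRNA-Arg-TCG, and unadjusted p under 0.05 then remained for 4 and 2 rising families. Without the first untreated library 31 families passed, and without the second 35; tRNA-Gln-TTG, tRNA-Leu-AAG, tRNA-Glu-CTC and tRNA-Leu-TAG missed the threshold without the first (adjusted p = 0.179, 0.469, 0.176 and 0.140), and tRNA-Leu-AAG without the second (0.0556). Without the second untreated library tRNA-Ala-CGC rose by 3.39 and tRNA-Thr-CGT by 3.29, and tRNA-Gly-TCC rose by 5.29 and 3.88 without the first and second treated library; without the first untreated one it had 0 untreated counts, as had tRNA-Gln-TTG, tRNA-Leu-AAG and tRNA-Glu-CTC, so that the size of their rise is not measured there. With sites above 500 counts left out, 3 families rose and 1 fell; of the 12 rises 2 passed there, tRNA-Gln-TTG (5.50) and tRNA-Thr-CGT (3.86), and 10 did not. Of these, tRNA-Leu-TAG (3.43), tRNA-Thr-AGT (2.34) and tRNA-Asn-GTT (1.93) changed by a similar or larger amount. The changes of tRNA-Gly-TCC (3.52), tRNA-Glu-CTC (2.88) and tRNA-Gln-CTG (2.13) were smaller. Those of tRNA-Leu-AAG (1.01), tRNA-Ala-AGC (0.98) and tRNA-Ala-CGC (0.93) were smaller still, and tRNA-Asp-GTC turned to -0.05. With no filter beyond 1 count, 11 of the 12 rises kept their call.

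**Figure D2:**
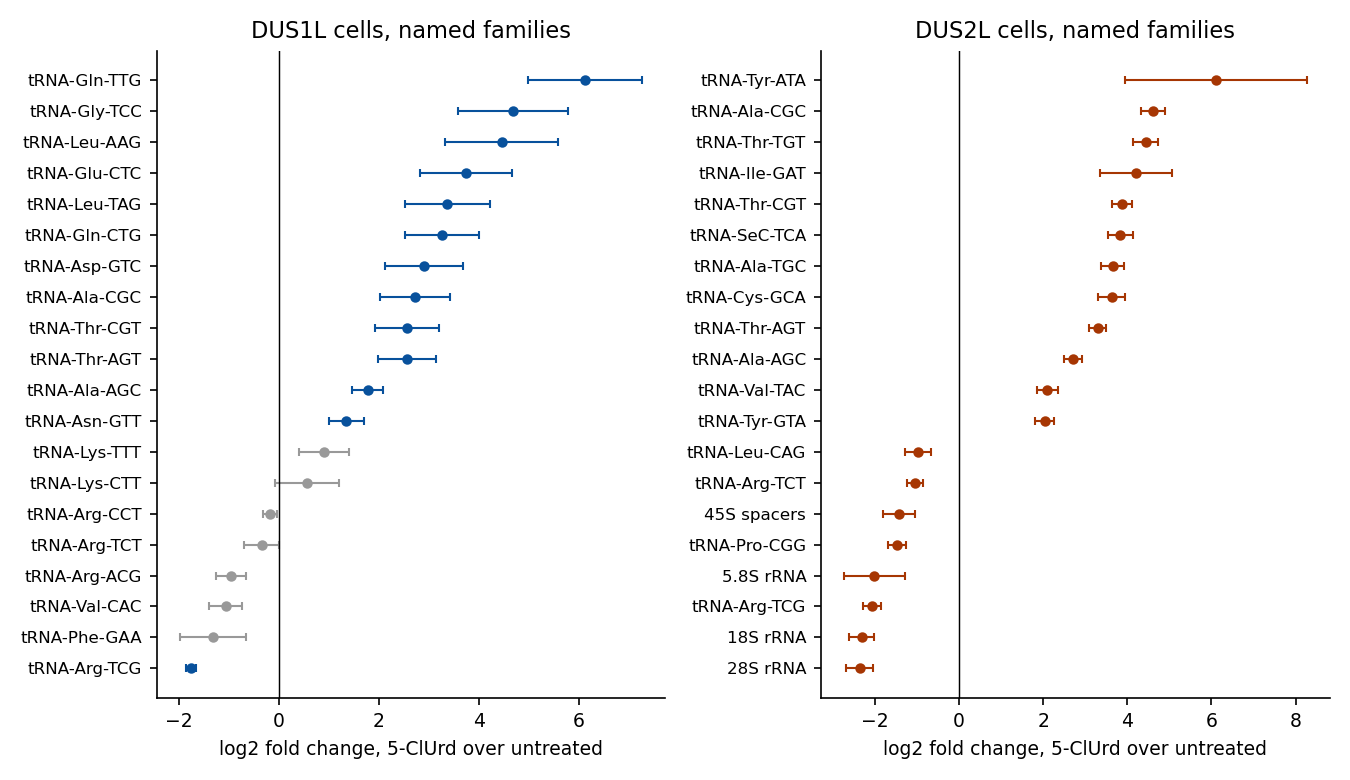
Log2 fold changes (5-ClUrd over untreated, total-count scaling) of the named families in DUS1L cells (left) and DUS2L cells (right). Points are edgeR estimates and bars their SE; coloured points passed an adjusted p of 0.05, and tRNA-Arg-TCG lies at -1.76 in DUS1L and -2.07 in DUS2L, while tRNA-Lys-CTT and tRNA-Lys-TTT of DUS1L turn negative with TMM or DESeq2 scalings.

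In DUS2L cells, all 3 alanine and all 3 threonine tRNA families rose with 5-ClUrd, and 4 of 5 rRNA families and tRNA-Arg-TCG fell. tRNA-Ala-CGC, with 4 genes on chromosomes 2 and 6, rose from 0.0170% ± 0.00227 to 0.419% ± 0.0397 of counts (log2 4.61 ± 0.28, adjusted p = 2.15e-05; SD, n = 2 each). tRNA-Thr-TGT rose from 0.0511% ± 0.0147 to 1.10% ± 0.192 (log2 4.44 ± 0.30, adjusted p = 2.48e-05). tRNA-SeC-TCA, the selenocysteine tRNA, rose by 3.83 ± 0.30 and tRNA-Cys-GCA by 3.63 ± 0.33 on the log2 scale. tRNA-Arg-TCG fell by 2.07 ± 0.22, from 3.47% ± 0.165 to 0.828% ± 0.117 (adjusted p = 0.000266).

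In this comparison 29 of 55 families rose and 13 fell, each separated in every library. tRNA-Thr-CGT rose by 3.87, tRNA-Ala-TGC by 3.65, tRNA-Thr-AGT by 3.29 and tRNA-Ala-AGC by 2.72 on the log2 scale. tRNA-Val-TAC rose by 2.10, tRNA-Tyr-GTA by 2.04 and tRNA-Ile-GAT by 4.21, the last from 6 and 12 untreated to 163 and 638 treated counts (4.87 without the first treated library and 2.88 without the second). tRNA-Tyr-ATA had 1 untreated and 189 treated counts, a ratio of 77.8 with a 95% counting interval of 13.8 to 3089. Among the falls, 28S rRNA changed by -2.35 ± 0.32, 18S rRNA by -2.31 ± 0.30, 5.8S rRNA by -2.01 ± 0.72 and the 45S spacers by -1.42 ± 0.37 (-2.92 and -2.06 for the last 2 without the second treated library). tRNA-Pro-CGG fell by 1.47, tRNA-Arg-TCT by 1.04 and tRNA-Leu-CAG by 0.98.

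The 6 alanine and threonine families, tRNA-Arg-TCG, 28S rRNA, 18S rRNA and tRNA-Pro-CGG passed with the same sign under every alternative that tested them, with tRNA-Arg-TCG at -3.29 without sites above 500 counts. TMM scaling moved the median family by -0.65 and gave 19 rises and 21 falls, and DESeq2 size factors moved it by -0.75 and gave 18 and 21. One fit of all 8 libraries kept 21 of the 29 rises and 6 of the 13 falls. More named falls than the 45S spacers given below therefore missed the threshold there. tRNA-Tyr-ATA missed the threshold with DESeq2 size factors (adjusted p = 0.0540) and without either untreated library (0.236 and 0.235), and its change was 6.83 without the first and 4.35 without the second treated library. Without the second untreated library 26 families passed; 5.8S rRNA missed the threshold without either untreated library (adjusted p = 0.202 and 0.393), tRNA-Leu-CAG without the second (0.169), tRNA-Arg-TCT and tRNA-Leu-CAG without sites above 500 counts (0.675 and 0.0597), and the 45S spacers in one fit of all 8 libraries (0.110).

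Of the lists fixed in advance, 3 had members in the data. In DUS1L cells the 48 cytosolic tRNA families had a median log2 change of 1.75 and a camera p of 0.170. Of these, 12 were higher and 1 lower, over all families and adjusted over the list alone, against 2 and 10 in DESeq2's Wald test. The 5 rRNA families had a median of 0.36 and a mean of 0.28 while camera placed them lower than the rest (adjusted p = 0.170); edgeR and DESeq2's Wald test called 0 of 5, and 0 had an unadjusted p under 0.05. Type II tRNAs (leucine, serine and selenocysteine, which have a long variable arm) had a median of 2.68, a camera p of 0.0293 and an adjusted p of 0.0880. 2 of these 10 type II families rose, and 6 rose when adjusted over the list alone; 8 had an unadjusted p under 0.05, and DESeq2's Wald test called 0. The list of 48 reached a camera p of 0.0359 without the first treated library. Type II tRNAs reached adjusted p of 0.0140 and 0.00755 without the first and second treated library, 0.0130 without the second untreated one and 0.00567 with TMM factors, against 0.408 with an estimated correlation.

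In DUS2L cells the 50 tRNA families lay higher than rRNA (median 0.92, camera adjusted p = 0.00152; adjusted p = 0.212 with an estimated correlation), with 29 higher and 9 lower, against 18 and 16 in DESeq2's Wald test. The 5 rRNA families lay lower (median -2.01, adjusted p = 0.00152; adjusted p = 0.294 with an estimated correlation), with 4 lower and 5 in the Wald test. Because every family is either tRNA or rRNA, these list tests are not independent. Type II tRNAs had a median of -0.19 and a mean of 0.26, with 3 higher and 4 lower (camera adjusted p = 0.247), against 1 and 6 in the Wald test. Adjusted over the list alone, the counts of these 3 DUS2L lists were the same.

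The responses of the 2 enzymes' cells were compared in one fit over all 8 libraries, as the 5-ClUrd effect in DUS2L minus that in DUS1L. tRNA-Cys-GCA (difference of log2 fold changes 3.38 ± 0.83), tRNA-Val-TAC (2.65 ± 0.73), tRNA-Thr-TGT (2.47 ± 0.52), tRNA-Met-CAT (1.97 ± 0.51) and tRNA-Val-CAC (1.43 ± 0.40) responded more positively in DUS2L. 3 of 5 leucine families and both glutamine families responded more negatively in DUS2L, led by tRNA-Leu-CAG (-5.12 ± 1.01). tRNA-Leu-TAG differed by -4.09 ± 0.59 and tRNA-Glu-CTC by -3.85 ± 0.79. The fitted differences of tRNA-Leu-AAG (-4.84 ± 0.86) and tRNA-Gln-TTG (-4.15 ± 0.72) depend on 1 untreated DUS1L count each. The others rest on few untreated DUS1L counts too: 5 and 2 for tRNA-Leu-CAG, 6 and 0 for tRNA-Glu-CTC, and 13 and 1 for tRNA-Leu-TAG.

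In total 6 families were higher and 10 lower of 55, and 25 had an unadjusted p under 0.05. With TMM factors 15 differences were lower and 0 higher, with 0 higher at an unadjusted p under 0.05 as well; DESeq2 size factors gave 4 higher and 15 lower, and DESeq2's Wald test 5 and 17, without tRNA-Val-CAC (0.175). The higher tRNA-Cys-GCA, tRNA-Val-TAC, tRNA-Thr-TGT, tRNA-Met-CAT and tRNA-Val-CAC had adjusted p of 0.201, 0.284, 0.180, 0.423 and 0.761 with TMM factors. Leaving out 1 library gave 8 and 5 calls without the first and second treated DUS1L library, 26 and 28 without the untreated ones, and 8 and 7 without the first and second untreated DUS2L library. tRNA-Leu-TAG kept its call in every alternative run, whereas tRNA-Leu-AAG and tRNA-Gln-TTG lost theirs without the first untreated DUS1L library (adjusted p = 0.188 and 0.279), as did tRNA-Glu-CTC (0.0845), and tRNA-Leu-CAG and tRNA-Glu-CTC missed the threshold without the second treated DUS1L library (0.0650 in both). Without the first untreated DUS1L library the differences of tRNA-Cys-GCA, tRNA-Val-TAC and tRNA-Leu-CAG were 2.02, 1.65 and -2.80, the last resting on 2 untreated DUS1L counts, and without the second those of tRNA-Cys-GCA and tRNA-Leu-CAG were 3.99 and -5.76. The 5 named more positive families missed the threshold without either treated DUS1L library (0.0554 to 0.118) and without the second untreated DUS2L library (0.0903 to 0.103). All but tRNA-Thr-TGT missed it without the first untreated (0.0668 to 0.115) and the second treated DUS2L library (0.0528 to 0.108), and tRNA-Val-TAC and tRNA-Val-CAC without the first treated one (0.0803 and 0.0925). Without sites above 500 counts tRNA-Leu-AAG (-1.45, adjusted p = 0.362), tRNA-Thr-TGT (0.96, 0.438), tRNA-Glu-CTC (-2.24, 0.0956), tRNA-Leu-CAG (-3.42, 0.0808), tRNA-Met-CAT (2.34, 0.0560) and tRNA-Val-TAC (3.01, 0.0569) missed it. For tRNA-Leu-AAG and tRNA-Glu-CTC only DUS2L libraries could reach that count at a site.

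Among treated libraries, DUS2L held far more proline, glutamate and glycine tRNA than DUS1L, and DUS1L held more arginine, alanine and tyrosine tRNA. These differences were present without 5-ClUrd too, in a comparison chosen after the data were seen. The untreated and treated differences between enzymes had the same sign in 54 of 55 families. Their median size on the log2 scale was 3.58 untreated and 2.10 treated. tRNA-Pro-CGG took 0.526% ± 0.0843 of treated DUS2L counts and 0.000519% ± 4.80e-05 of treated DUS1L counts (log2 9.89 ± 0.43, adjusted p = 1.18e-06; SD, n = 2 each). tRNA-Pro-CGG and tRNA-Pro-AGG each had 7 counts in the treated DUS1L libraries together. tRNA-Glu-TTC took 5.47% ± 1.03 against 0.0214% ± 0.0109. tRNA-Arg-TCT took 0.383% ± 0.0335 of DUS2L counts against 8.76% ± 0.142 of DUS1L counts (log2 -4.52 ± 0.39, adjusted p = 2.92e-05). tRNA-Phe-GAA was lower in DUS2L by -3.60 ± 0.69 on the log2 scale.

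Of 55 families, 21 were higher in DUS2L and 15 lower. All 3 proline, all 3 glycine and both glutamate families were higher, and all 5 arginine, all 3 alanine and both tyrosine families were lower. tRNA-Pro-TGG differed by 8.84, tRNA-Pro-AGG by 8.76 and tRNA-Leu-AAG by 6.62. tRNA-Arg-ACG differed by -3.26, tRNA-Arg-TCG by -2.90 and tRNA-Ala-TGC by -2.84. The 10 named families kept their sign and their call in all 160 alternatives, with tRNA-Pro-TGG at 9.62 and tRNA-Glu-TTC at 8.64 without the second treated DUS1L library, and tRNA-Leu-AAG at 8.35, tRNA-Arg-TCT at -5.25, tRNA-Phe-GAA at -6.57, tRNA-Arg-ACG at -5.64 and tRNA-Arg-TCG at -4.93 without sites above 500 counts; the amino acid grouping was chosen after the values were seen. Alternatives that left out an untreated library acted on this comparison almost only through the estimated spread, so the sign could hardly turn there. Enzyme, cell line and the making of the files cannot be told apart in this comparison.

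**Figure D3:**
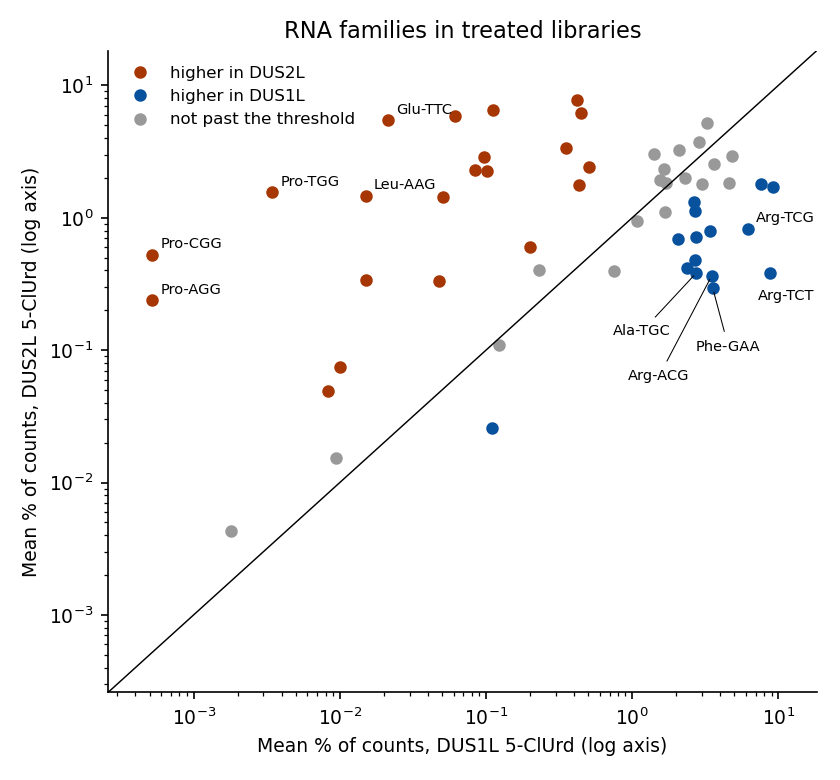
Mean share of sense counts (%, log axes) of each RNA family in treated DUS1L (horizontal) and treated DUS2L libraries (vertical), with the line of equality. Colours mark families past an adjusted p of 0.05, 21 higher in DUS2L and 15 higher in DUS1L; tRNA-Pro-CGG lies at 0.000519% and 0.526%, and tRNA-Arg-TCT at 8.76% and 0.383%.

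Positions 16 and 17, where DUS1-type enzymes act, took more of the DUS1L tRNA counts with 5-ClUrd, as did most of the D arm around them. Their share was 2.23% ± 0.357 untreated and 4.74% ± 0.00189 treated (SD, n = 2 each), a difference of 2.51 points. The rise was not particular to them: 14 of the other 17 D-arm positions were also higher in both treated DUS1L libraries. The median ratio of treated to untreated share was 2.63 for these 17, against 1.68 at position 16 and 3.35 at position 17. In DUS2L cells the share at 16 and 17 was 7.19% ± 0.120 untreated and 6.37% ± 0.240 treated. Position 20, the textbook DUS2 target, took 2.35% ± 0.436 and 2.42% ± 0.0688 of DUS2L tRNA counts, and 2.91% ± 0.668 and 2.37% ± 0.0220 of DUS1L tRNA counts. The whole window of positions 8 to 26, called the D arm here, held 45.9% ± 1.74 and 48.7% ± 0.136 in DUS2L. In DUS1L it held 33.3% ± 11.3 untreated and 9.72 points more with 5-ClUrd (treated SD 0.493). Without the first untreated library the D-arm difference was 1.72 points in DUS1L and 4.05 in DUS2L, and without the second 17.7 and 1.59 points.

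The differences of these pooled shares at position 20 were smaller than the combined SD of the groups in both enzymes. So was that of the D arm in DUS1L, but its window includes position 26. That position alone held 7.22% and 20.7% of tRNA counts in the untreated DUS1L libraries, and 6.30% and 6.52% in the treated ones. Its untreated SD of 9.55 goes into that of the window, and its fall counts against the rise of the other positions. Within single families, both treated DUS2L libraries exceeded both untreated ones at position 20 in 21 of 42 families. In DUS1L 13 of 21 families did so at positions 16 and 17. Chance alone would separate a share of 0.333 of families, rises and falls together. The same count was not made at other positions, so these counts do not single out the target positions. Falls were not counted, such as tRNA-His-GTG at position 20 in DUS2L (8.25% to 4.47%). Several untreated shares were 0, and families are not independent replicates. Where both treated libraries lay on one side of both untreated ones, the exact two-sided permutation p was 0.33333, the smallest possible. Positions were counted along each reference from its 5′ end, without alignment to standard tRNA numbering, so that a D loop of another length shifts the target by a base or more. With 1 nt to either side the position 20 difference of DUS1L was 0.995 points, and with each site counted once the 16 and 17 difference of DUS1L was -0.326 points.

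**Figure D4:**
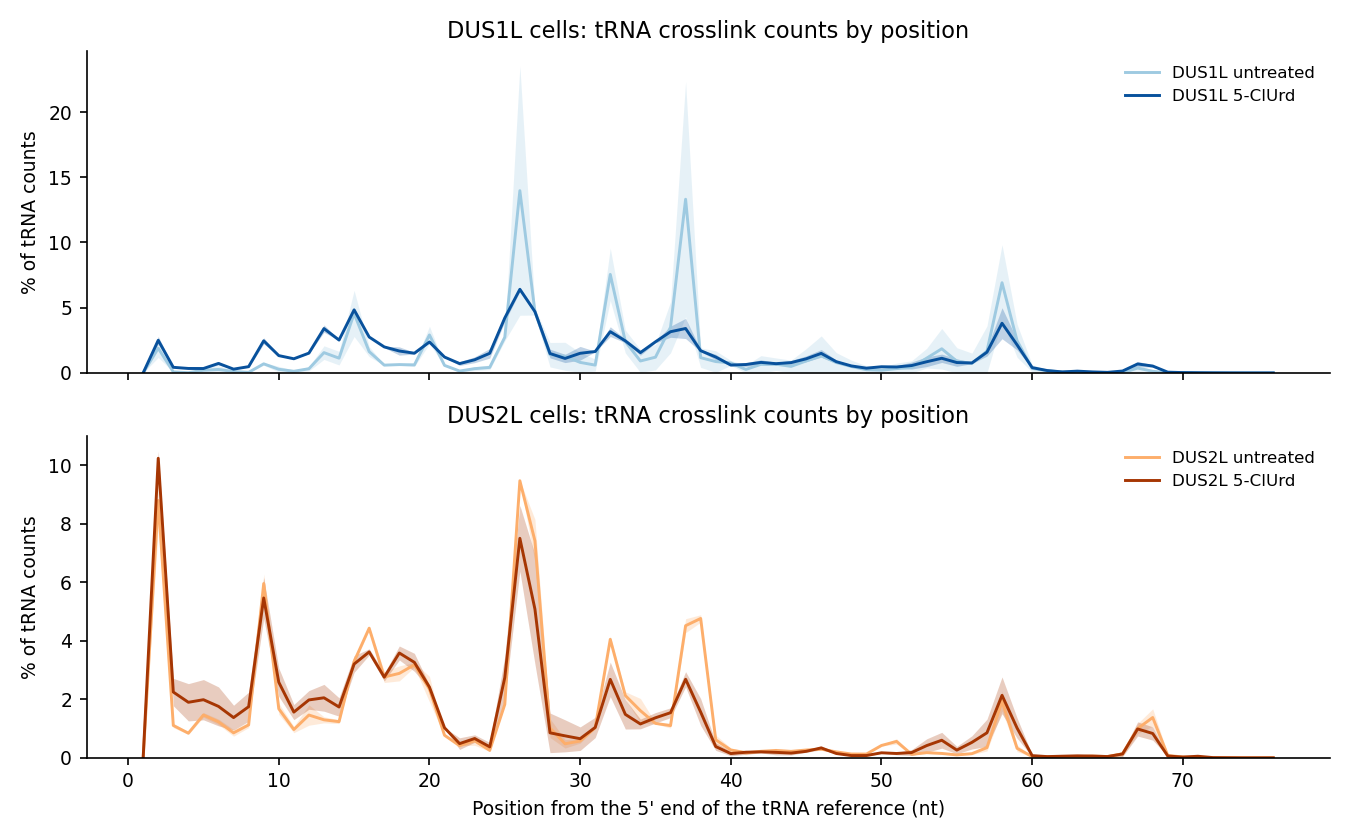
Share of tRNA crosslink counts (%) at each position from the 5′ end of the tRNA reference, in DUS1L cells (top) and DUS2L cells (bottom). Lines are means of 2 libraries and bands 1 SD; position 2 stands at 10.2% in treated DUS2L libraries, position 26 at 6.41% in treated DUS1L and 7.50% in treated DUS2L libraries, and position 20 at 2.37% and 2.42%.

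At single positions of tRNA families, 579 of 1921 sites rose and 30 fell in DUS1L, and 517 of 1927 rose and 101 fell in DUS2L. These fold changes are scaled to tRNA and rRNA counts together, while the site shares below are of tRNA counts. Scaled to tRNA site counts, 574 rose and 29 fell in DUS1L, and 436 rose and 122 fell in DUS2L. The sites with the highest treated DUS1L shares lay in tRNA-Asn-GTT, tRNA-Ala-AGC, tRNA-Arg-CCT, tRNA-Arg-TCG and tRNA-Ser-TGA. Position 32 of tRNA-Arg-CCT fell from 5.08% ± 2.94 to 0.718% ± 0.133 of tRNA counts (log2 -2.82 ± 0.61, adjusted p = 0.0218). In tRNA-Arg-TCG, position 26 fell by 3.09 ± 0.72 and position 37 by 2.58 ± 0.70, while position 58 (-1.50) had an adjusted p of 0.0948. Without the first and second untreated library position 26 changed by -3.82 and -1.53 and position 37 by -3.22 and -1.41, and position 32 of tRNA-Arg-CCT by -2.06 without the second. Position 58 of tRNA-Arg-TCG passed as a fall with TMM factors (-2.69), DESeq2 size factors (-2.50) and DESeq2's Wald test (-2.50), in one fit of all 8 libraries (-1.51), without the second untreated library (-1.77) and without sites above 500 counts (-5.55, from 20 and 0 untreated and 2 and 3 treated counts). Position 25 of tRNA-Ala-AGC rose by 2.90 ± 0.93 to 0.630% ± 0.0847, a rise that missed the threshold with TMM factors (adjusted p = 0.275), without the first untreated library (0.0513) and without sites above 500 counts (0.252), where 0 untreated and 14 and 3 treated counts are left and the size of the rise is not measured. Position 17 of tRNA-Ala-AGC (1.47, adjusted p = 0.300) and position 36 (0.09), position 27 of tRNA-Asn-GTT (-0.06), position 58 of tRNA-Arg-CCT (-0.28) and position 26 of tRNA-Ser-TGA (0.79) did not pass. Without the second untreated library, position 17 of tRNA-Ala-AGC (4.67, adjusted p = 0.00145) and position 26 of tRNA-Ser-TGA (3.89, adjusted p = 0.00242) passed as rises. Without the first and second treated library, adjusted p were 0.160 and 0.0754 for position 32 of tRNA-Arg-CCT, 0.0967 and 0.0589 for position 26 and 0.259 and 0.135 for position 37 of tRNA-Arg-TCG, and 0.359 and 0.405 for position 25 of tRNA-Ala-AGC.

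Of the 10 sites with the highest treated DUS2L shares, 4 were position 26 of serine tRNAs and 3 lay in tRNA-Gly-TCC. Position 3 of tRNA-Gly-TCC rose by 2.71 ± 0.29 to 0.712% ± 0.0832 (adjusted p = 2.34e-18) and its position 9 by 1.44 ± 0.24, while position 2 (0.20, adjusted p = 0.418) did not pass. Position 26 rose in tRNA-Ser-AGA (0.58 ± 0.19) and tRNA-Ser-GCT (1.10 ± 0.24), fell in tRNA-Ser-CGA (-0.59 ± 0.19) and narrowly missed the threshold in tRNA-Ser-TGA (-0.38 ± 0.16). Position 27 of tRNA-Leu-CAA fell by 0.96 ± 0.15, and position 32 of tRNA-Arg-CCT and position 58 of tRNA-Val-CAC rose by 0.65 and 0.59. With TMM factors the rises in tRNA-Ser-AGA, tRNA-Ser-GCT, tRNA-Arg-CCT and tRNA-Val-CAC missed the threshold (log2 0.01, 0.52, 0.07 and 0.03), and tRNA-Ser-TGA passed (-0.95). In one fit of all 8 libraries position 9 of tRNA-Gly-TCC and position 27 of tRNA-Leu-CAA missed it (adjusted p = 0.0769 and 0.141), the former also in DESeq2's Wald test (0.133), and without sites above 500 counts position 26 of tRNA-Ser-GCT and tRNA-Ser-CGA missed it at larger changes (1.84 and -1.45, adjusted p = 0.194 and 0.0925). In that setting position 2 of tRNA-Gly-TCC passed (4.18, from 2 and 2 untreated to 74 and 102 treated counts), and its positions 3 and 9 had 0 untreated counts, so that the size of their rise is not measured there. Without the first untreated library adjusted p were 0.0639 for tRNA-Ser-AGA, 0.0663 for tRNA-Arg-CCT and 0.436 for tRNA-Val-CAC, without the second 0.0905 for tRNA-Arg-CCT and 0.110 for tRNA-Ser-CGA, without the second treated one 0.187 for tRNA-Val-CAC and 0.129 for tRNA-Ser-CGA, and tRNA-Ser-TGA passed without the first treated one (0.0376).

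Rising sites were most frequent on the 5′ side of the acceptor stem and in the D arm, parts chosen after the values were seen. In DUS1L, 76 of 176 acceptor sites and 253 of 640 D-arm sites rose (Fisher's exact test, adjusted p = 0.000272 and 1.47e-09), against 83 of 522 sites of the variable and T arm (4.87e-17). In DUS2L, 98 of 174 and 242 of 689 rose (adjusted p = 4.87e-17 and 4.57e-09), against 92 of 597 in the anticodon arm (3.21e-14). At positions 16 and 17, 27 of 72 DUS1L and 31 of 86 DUS2L sites rose (adjusted p = 0.242 and 0.107) while 0 and 10 fell (0.780 and 0.0875), and at position 20, 15 of 35 and 15 of 40 (0.207 in both). Neighbouring sites are not independent, which these tests assume. TMM scaling gave 263 rises and 116 falls in DUS1L and 323 and 180 in DUS2L; the calls came to 40 without the first untreated DUS1L library and 341 without the first treated one, and to 196 and 106 without the first and second untreated DUS2L library.

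Peaks deposited for each library overlapped most between treated replicates. With at least 1 shared base on the same strand, the Jaccard index (shared over combined bases) was 0.353 between treated DUS1L replicates and 0.0612 between untreated ones, with 0.110 ± 0.0733 (SD of 4 pairs) between treated and untreated. For DUS2L it was 0.415, 0.289 and 0.220 ± 0.0269. DUS1L libraries had 126 and 37 untreated and 335 and 256 treated peaks, and DUS2L libraries 200 and 201 untreated and 225 and 300 treated ones. Of the treated peaks, 225 and 184 lay on tRNA in DUS1L and 165 and 184 in DUS2L, the rest on rRNA. Peak numbers differ with depth, and so does the overlap that can be reached.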

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

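The tests of explanations for the family differences were chosen after the results were seen. In 16 families the 5-ClUrd effect differed between DUS1L and DUS2L cells by a test of the difference itself (edgeR, adjusted p under 0.05). The effect was more positive in DUS2L for tRNA-Cys-GCA (difference of log2 fold changes 3.38), tRNA-Val-TAC (2.65), tRNA-Thr-TGT (2.47), tRNA-Met-CAT (1.97), tRNA-Val-CAC (1.43) and tRNA-Arg-CCT (1.15). It was more negative for tRNA-Leu-CAG (-5.12), tRNA-Leu-AAG (-4.84), tRNA-Gln-TTG (-4.15), tRNA-Leu-TAG (-4.09) and tRNA-Glu-CTC (-3.85). The other more negative families were tRNA-Asp-GTC (-3.23), tRNA-Ser-TGA (-2.96), tRNA-His-GTG (-2.70), 28S rRNA (-2.30) and tRNA-Gln-CTG (-2.03). With TMM factors none of the 6 more positive families passed in edgeR, and 0 families were more positive at an unadjusted p under 0.05, while DESeq2's Wald test called 4 of the 6. tRNA-Arg-CCT, 28S rRNA, tRNA-His-GTG, tRNA-Ser-TGA, tRNA-Asp-GTC and tRNA-Gln-CTG lie outside the naming rule and were chosen after their values were seen.

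The second untreated DUS1L library alone is argued against as the cause, since all 16 of these families kept their direction without it. The differences were then 3.99 for tRNA-Cys-GCA and -5.76 for tRNA-Leu-CAG. A thin untreated baseline is not excluded by this. Only the first untreated DUS1L library remains in that fit. It held 145380 counts, against 7395 in the second, and so was most of the baseline in the full fit too. A limit on the count per site in the deeper libraries stays open: without sites above 500 counts, 6 of the 16 passed in the same direction, 15 of 16 (all but tRNA-His-GTG) kept their sign, and the median size of the difference went from 2.83 to 2.15. The number alone would have met the prediction first written for such a limit. A second condition, a median size under 50% of that with all sites, was added after the 6 had been seen, so neither reading is decided. Sites high in either enzyme's libraries were left out of both. For tRNA-Leu-AAG and tRNA-Glu-CTC only DUS2L libraries could exceed 500 counts, so their loss says nothing on a limit in DUS1L. Different targets of the enzymes, different cell lines and different making of the files may each contribute, and the design holds no library that separates them.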

How the results depend on the processing

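Across the named families and sites, 261 of 406 DUS1L alternatives, 342 of 401 DUS2L alternatives, 115 of 160 for the difference between enzymes and all 160 between treated libraries kept direction and side of the threshold; direction turned in 26, 4, 0 and 0. Between treated libraries, leaving out an untreated library acted almost only through the estimated spread. Unless a construction is named, the cause was not tested for the changes that follow. TMM factors gave a camera p of 0.00189 for type II tRNA in DUS1L, and estimated correlation 0.0708 for tRNA in DUS2L. tRNA-Lys-CTT in DUS1L was -0.43 with TMM, -0.57 with DESeq2 size factors and -0.58 with DESeq2's Wald test, and tRNA-Lys-TTT -0.16, -0.42 and -0.42. In that order DUS1L sites past the threshold numbered 379, 369 and 385; position 36 of tRNA-Ala-AGC was -1.09, -0.89 and -0.91, position 26 of tRNA-Ser-TGA -0.37, -0.027 and -0.025, and position 2 of tRNA-Gly-TCC in DUS2L -0.38, -0.37 and -0.37 (-0.016 scaled to tRNA site counts). All 8 libraries in one fit gave 27 families in DUS1L and 27 in DUS2L. Without sites above 500 counts 4 DUS1L families passed, tRNA-Asp-GTC was -0.052, tRNA-Arg-ACG 0.069, position 27 of tRNA-Asn-GTT 0.38 and position 58 of tRNA-Arg-CCT 1.12. With no filter beyond 1 count 289 DUS2L sites passed.

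With each site counted once the tRNA share differed by -8.69 points in DUS1L and 19.6 in DUS2L, and at positions 16 and 17 by -0.326 in DUS1L; inside peaks the tRNA share differed by -1.21 and 8.22. With 1 nt to either side, positions 16 and 17 differed by 3.83 in DUS1L and -0.205 in DUS2L, position 20 by 0.995 in DUS1L and the D arm by 1.01 in DUS2L. As a mean over families, positions 16 and 17 differed by -1.23 and position 20 by 0.688 in DUS2L. At 50% overlap the Jaccard index of untreated DUS1L replicates was 0.04; among peaks above each list's median score it was 0.452 for treated DUS1L, 0.377 for untreated DUS2L, 0.251 for treated against untreated DUS2L and 0.486 for treated DUS2L.

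Leaving out 1 library, which also leaves fewer samples, gave these ranges in DUS1L: camera p 0.0359 to 0.587 for tRNA and 0.00252 to 0.112 for type II tRNA, 1 to 35 families, 40 to 853 sites, tRNA-Arg-TCT -0.81 to 0.37, tRNA-Lys-CTT -0.13 to 1.93, tRNA-Phe-GAA -2.06 to 0.23, position 27 of tRNA-Asn-GTT -0.26 to 0.12, positions 17 and 36 of tRNA-Ala-AGC 0.47 to 4.67 and -0.15 to 0.36, position 26 of tRNA-Ser-TGA -0.18 to 3.89 and position 58 of tRNA-Arg-CCT -1.11 to 2.09. DUS2L ranged over 26 to 46 families and 106 to 599 sites, and the difference between enzymes over 5 to 28 families. Depth limits DUS1L most: the second untreated library allows no share under 0.0407% to be told from 0.

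With the replicate number in the model (replicate block), 19 DUS1L families, 468 DUS1L sites, 38 DUS2L families, 464 DUS2L sites, 17 differences and 31 families between treated libraries passed, each within 1.5 times of the fit without it. The calls themselves overlapped less: 333 of the 609 DUS1L site calls and 462 of the 618 DUS2L site calls stayed. Among families 12 of 13 calls stayed in DUS1L and 38 of 42 in DUS2L. The same held for 15 of 16 differences and 31 of 36 calls between treated libraries. Of the named results, tRNA-Asn-GTT and position 25 of tRNA-Ala-AGC in DUS1L (adjusted p = 0.0977 and 0.0905), tRNA-Leu-CAG in DUS2L (0.0596) and the difference of tRNA-Val-TAC (0.0510) missed the threshold under it and no other call was lost, and position 58 of tRNA-Arg-CCT in DUS1L was 0.37. The numbers do not pair the samples, as no shared day is named; deviations of same-numbered libraries correlated at 0.0831 over 53 DUS1L families and 0.241 over 55 DUS2L families.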

Other observations

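The comparison of untreated libraries, the position groups and every test of an explanation here were chosen after the data were seen. Without 5-ClUrd the enzymes' libraries already differed in 49 of 55 families, 26 higher in DUS2L and 23 lower (edgeR, all 8 libraries in one fit). tRNA-Asp-GTC took 10.2% ± 0.681 of untreated DUS2L counts and 0.0522% ± 0.0163 of untreated DUS1L counts (log2 7.45 ± 0.30; SD, n = 2 each). tRNA-Arg-TCG took 3.47% ± 0.165 against 20.9% ± 0.414, and tRNA-Arg-CCT 0.873% ± 0.00856 against 10.3% ± 0.0587 (log2 -3.56 ± 0.15). Across the 55 families, the untreated and treated differences between enzymes had the same sign in 54 and a Pearson r of 0.935 (Spearman rho 0.947). 35 families passed in both in the same direction, and the median size was 3.58 untreated and 2.10 treated; families are not independent replicates. tRNA-Asp-GTC and tRNA-Arg-CCT were chosen here after their values were seen.

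tRNA-Arg-TCG fell with 5-ClUrd in both enzymes' cells. A limit on the count per site stays open as a cause. Without sites above 500 counts the smaller of the 2 enzymes' falls was still -1.68, but lower counts may be limited too. Between the first DUS1L libraries, sites with at least 300 but under 500 untreated counts had a median ratio of treated to untreated counts of 1.92. The ratio of the totals was 5.71, and the sorting by count was not corrected for. Position 26 of tRNA-Arg-TCG kept only 3 and 0 untreated and 1 and 0 treated DUS1L counts in that setting. The smallest change over both enzymes and both other scalings was -2.71, which met the condition written against scaling to total counts as the cause. That condition could hardly fail. TMM and DESeq2 size factors moved the median family by -1.03 and -1.25 in DUS1L and by -0.65 and -0.75 in DUS2L. A fall could only deepen there, so this test does not decide on the scaling. A lower contact of the tagged enzymes with this family relative to others may underlie the fall, a hypothesis found on these data and not tested. How much tRNA-Arg-TCG the cells hold was not analysed here.

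Positions 9, 26, 32, 37 and 58, picked because many tRNAs carry modified bases there, together held more tRNA counts than an even spread. These 5 of 76 positions held 42.5% ± 17.6 of untreated and 19.2% ± 2.73 of treated DUS1L tRNA counts, and 25.9% ± 0.365 and 20.5% ± 0.643 of DUS2L tRNA counts (SD, n = 2 each), against 6.58% for an even spread. This does not hold for each of them: position 9 held 0.696% ± 0.0971 of untreated DUS1L tRNA counts, where an even spread gives 1.32%. Positions outside the 5 were high as well, such as position 2 in DUS2L (8.79% ± 0.941 untreated and 10.2% ± 0.248 treated) and position 27 in treated DUS1L (4.70% ± 0.179). Reverse transcription stops at naturally modified bases that need no 5-ClUrd stay open as an explanation. The treated share was lower by 5.46 points in DUS2L (treated minus untreated -5.46) and by 23.2 in DUS1L, as such stops would give, but the DUS1L difference was -35.6 without the first and -10.8 without the second untreated library, and position 9 alone rose in DUS1L to 2.46% ± 0.234. The condition that no single position rises was added after that rise had been seen. The families' shares change as well, and contact of the enzymes at these positions without the analogue would give the same values. A limit on the count per site was not separated from this either. Between the first DUS1L libraries, sites with at least 900 untreated counts had a median ratio of 1.02, against 5.71 for the totals.

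A hypothesis was that 5-ClUrd moves part of the families alike whichever enzyme is induced. Across 53 families the DUS1L and DUS2L log2 fold changes, from separate libraries, had a Pearson r of 0.272 (permutation p = 0.0490) and a Spearman rho of 0.278 (p = 0.0441). Without sites above 500 counts r was 0.370 (permutation p = 0.00616) and rho 0.357 (p = 0.00953). 8 families rose in both, where independent lists of these sizes would share 6.57, and tRNA-Arg-TCG fell in both. The correlation is across families, which are shares of one total and no independent replicates, so the values are consistent with a common part without showing one.

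Sites with high untreated counts grew less than the library totals with 5-ClUrd, in libraries compared by replicate number. Between the first DUS1L libraries the median ratio of treated to untreated counts was 16.2 for sites with 5 to 19 untreated counts, 6.58 for 20 to 99 and 1.02 for sites with at least 900, while the sense counts of these libraries differed by a factor of 5.71. Between the second DUS1L libraries, whose sense counts differed by a factor of 73.6, it was 54.2 for 5 to 19 untreated counts and 24.7 for 20 to 99. Between the first DUS2L libraries the ratio was 0.2 for sites with 5 to 19 untreated counts and 1.48 for 20 to 99, against 2.85 for their sense counts, and from 100 untreated counts up it went down from 3.17 over 2.29 to 1.38 in successive count classes. Between the second DUS2L libraries it was 0.333 and 0.879, then 1.78, 1.70 and 0.982, against 2.11. Sites sorted by the count of one library tend towards lower counts in another by chance alone, which was not corrected for. The highest site count per library was 555 in the second untreated DUS1L library and between 1061 and 1436 in the others.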
